A study of Pisolithus microcarpus and Eucalyptus grandis
Pisolithus microcarpus with 23 samples.

How the data were processed

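RNA from 4 strains of the ectomycorrhizal fungus Pisolithus microcarpus (Si9, R4, R10 and MW3) was sequenced in 23 libraries. Per the labels' protocols, a 0.25 cm2 piece of mycelium was laid on the root of a 1-month-old Eucalyptus grandis seedling in a 9 cm dish of diluted MMN medium with 0.1% glucose. Colonised root tips (ECM) and control mycelium grown without a root (free-living mycelium, FLM) were taken after 4 weeks. Total RNA was extracted with a plant RNA kit and made into Illumina cDNA libraries, per the labels' protocols. Each group held 3 libraries except Si9 ECM, which held 2 (replicates 1 and 3). The labels call the libraries biological replicates and do not say whether they came from separate dishes, so the p-values measure the spread between these libraries.

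Each deposited file lists 21064 protein IDs of the JGI gene set Pismi1 and gives for each a whole-number count of uniquely mapped reads, per the file headers. These counts were not normalised by the authors, as their totals differ between libraries. The files also give length-scaled transcript abundances (TPM), per the file headers, with about the same sum in each of the 17 libraries of Si9, R10 and MW3. In the 6 R4 libraries the deposited TPM values are whole numbers, and they were treated as a rounded score. The aligner, the counting program and their settings are not given in the sources used here. All strains were counted on 1 gene set, so sequence differences between a strain and that gene set can shift its counts. The files do not pair the protein IDs with gene names, and no annotation was used, so 26 gene lists fixed by product name had no members and no gene set test was run. At most 2 IDs higher and 2 lower are named per comparison.

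Every comparison used the unique read counts. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), libraries were scaled by the trimmed mean of M values (TMM), and differences were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust dispersion) and Benjamini-Hochberg adjustment at 0.05. ECM and FLM were compared within each strain in a separate fit. Joint fits asked whether the ECM to FLM difference differed between strains (all 23 libraries), and whether strains differed in FLM and in ECM. Likeness between strains was described by the overlap of calls, beside the overlap of independent lists, and by correlations across genes. Values within a strain are given as counts per 1000000 reads (CPM) after TMM, with the SD between libraries. Levels compared between strains are CPM by library totals, without TMM, while the tests of strain differences used TMM. A fold against a group with no read in any library was computed against 3 reads pooled over that group, on the same TMM scale as the CPM within a strain, and is a lower bound. Folds against a group with 10 or fewer pooled reads are on that scale and carry an exact binomial 95% interval, which covers counting error only.

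The proteins named in each strain were those with the largest log2 fold change among proteins past the threshold, with ECM and FLM libraries not overlapping and at least 10 CPM in the higher group. For all strains together they were those with the largest smallest change, and for the joint tests those with the smallest p. This rule, the groups, the tests and most alternatives were set before the data were examined. Corrections for gene length, an equal depth and scaling by library totals were added after the data were seen. Relative gene lengths came from the ratio of unique reads to TPM.

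Library totals ranged from 5046321 to 18733679 unique reads. No pair of replicate libraries agreed within sampling noise, with chi-square values per degree of freedom from 1.16 to 7.83 over 22 pairs, so none was treated as a library deposited more than once. This check does not show whether the libraries came from separate samples. Across proteins, replicate libraries correlated at Pearson r from 0.996 to 0.999. Of 6678 proteins with at least 100 reads in each of the 17 libraries with unrounded TPM, 615 (9.21%) had a ratio of unique reads to TPM that varied by over 5% between libraries. Such variation leaves open how reads shared with similar genes were counted, and the value of protein 686019 (30.4%) is uncertain for that reason. Most named proteins, such as 688067 and 636179, lacked 100 reads in each of these libraries and could not be checked this way.

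The fits were tested on simulated counts with known changes. Of 50 proteins changed 2-fold, 47 were recovered with the Si9 libraries, 47 with R4, 47 with R10 and 46 with MW3. Of 50 changed 1.2-fold, 12 were recovered with Si9, 22 with R4, 14 with R10 and 22 with MW3. The joint tests recovered 46 of 50 proteins changed 2-fold for the strain-by-tissue difference, 45 for FLM and 45 for ECM. Unchanged proteins were called in at most 0.0924% of cases (MW3). The simulated data held few changed proteins, 50 at each fold, and gave all proteins of a fit the same spread. In the real ECM to FLM comparisons 40.7% (Si9) to 72.6% (MW3) of proteins were called. The simulated share is therefore not the error rate of the real calls.

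The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors, no filter, a filter of 50 counts, the replicate number as a block, a joint fit of all strains, a 2-fold minimum, an adjusted p of 0.01 and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.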

Results

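Gene expression in 4 strains of Pisolithus microcarpus, a fungus that forms ectomycorrhizas on Eucalyptus roots, was measured by RNA sequencing in colonised root tips (ECM) and in mycelium growing alone (FLM). The files listed 21064 proteins, of which 15816 had a unique read in at least 1 of the 23 libraries. FLM libraries held 6372015 to 7659197 unique reads in Si9, 12992664 to 13670790 in R4, 11156759 to 14165873 in R10 and 11285634 to 13717499 in MW3. ECM libraries held 5046321 to 5407530 in R4, 7370056 to 7911205 in R10 and 7056810 to 8084013 in MW3, and the Si9 pair held 6406714 and 18733679. Libraries grouped by strain before tissue, and the first 3 principal components held 34.3%, 25.1% and 23.1% of the variance over 13830 proteins.

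**Figure D1:**
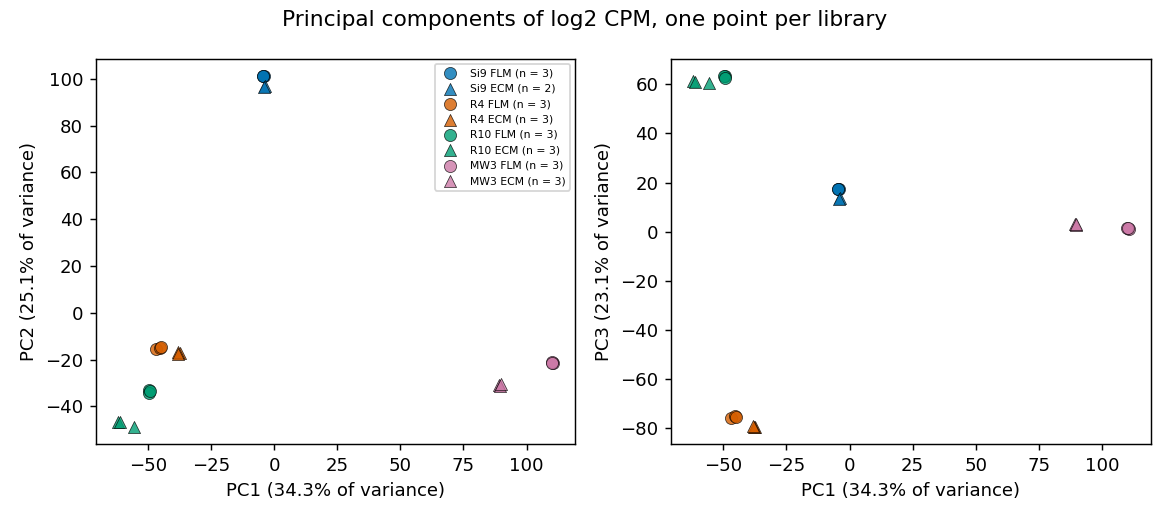
Principal components of log2 CPM for the 23 libraries (circles FLM, triangles ECM, colours strains), with axes in component units and the share of variance on each axis. Libraries of a strain lie together, and R10 ECM replicate 3 lies at -55.5 on the first component against -62.1 and -61.3 for the other R10 ECM libraries.

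The first question was how each strain's expression in the root tip differed from that of its free-living mycelium. In Si9, protein 689604 rose from 0.567 ± 0.192 CPM (SD, n = 3) in FLM to 47.7 ± 0.371 CPM (n = 2) in ECM, a log2 change of 6.33 ± 0.21 (SE). Protein 689601 rose from 0.935 ± 0.357 to 19.99 ± 3.33 CPM (log2 change 4.47 ± 0.25). Protein 572741 fell from 192 ± 9.47 to 10.999 ± 0.545 CPM, 17.2-fold lower in ECM, and protein 686019 fell from 819 ± 38.3 to 126 ± 9.14 CPM, 6.40-fold lower. The value of 686019 is uncertain, as its ratio of unique reads to TPM varied by 30.4% between libraries. The 228 proteins that rose at least 2-fold took 1.17% of the reads in FLM and 3.06% in ECM, and the 140 that fell at least 2-fold took 1.96% and 0.744%. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment the 4 named proteins had adjusted p values of at most 1.19e-29. The test called 2435 proteins higher and 2670 lower in ECM of 12548 tested (40.7%), and 75.6% of those calls were under 1.5-fold. Without ECM replicate 3, the deepest library, it called 1710 higher and 1717 lower, with the lone ECM library assumed to vary like the FLM libraries.

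In R4, proteins 685512 and 17110 were nearly silent in FLM and present in ECM. Protein 685512 had 4 pooled reads in the 3 FLM libraries and rose from 0.102 ± 0.115 to 43.7 ± 4.58 CPM (n = 3 each), a ratio of pooled reads of 431 (95% interval 167 to 1590). Protein 17110 had 3 pooled reads in FLM and rose to 29.3 ± 1.28 CPM, a ratio of 386 (131 to 1880). Both ratios moved when 1 FLM library was left out. That of 685512 was 284 (110 to 1050) without FLM replicate 1 and 1150 (205 to 45400) without FLM replicate 3, and that of 17110 was 780 (139 to 30900) without FLM replicate 2 and 257 (87.3 to 1250) without FLM replicate 3. Protein 25241 fell from 23.3 ± 2.18 to 1.02 ± 0.252 CPM, 22.5-fold lower in ECM, and protein 20216 fell from 20.4 ± 1.89 to 0.894 ± 0.107 CPM, also 22.5-fold lower. Proteins that rose at least 2-fold (452) went from 3.18% of the reads in FLM to 10.1% in ECM, and those that fell at least 2-fold (542) went from 11.1% to 4.24%. The edgeR quasi-likelihood test gave the 4 named proteins Benjamini-Hochberg adjusted p values of at most 1.88e-23. It called 3561 proteins higher and 3597 lower of 12389 tested (57.8%), 60.6% of them under 1.5-fold.

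In R10, both named proteins that rose became abundant. Protein 688067 rose from 38.5 ± 4.32 to 4479 ± 173 CPM (n = 3 each), 117-fold higher in ECM, and protein 677552 rose from 286 ± 29.5 to 9305 ± 317 CPM, 32.5-fold higher. Protein 11043 fell from 102 ± 8.60 to 2.33 ± 0.994 CPM, 42.9-fold lower, and protein 636179 fell from 446 ± 13.0 to 10.7 ± 1.08 CPM, 41.7-fold lower. The 461 proteins that rose at least 2-fold took 4.89% of the reads in FLM and 15.5% in ECM, and the 661 that fell at least 2-fold took 10.3% and 2.64%. The edgeR quasi-likelihood test gave the 4 named proteins Benjamini-Hochberg adjusted p values of at most 1.77e-14, and called 3176 proteins higher and 3241 lower of 12565 tested (51.1%), 57.9% of them under 1.5-fold. FLM replicate 3 stood apart from the other R10 FLM libraries (chi-square per degree of freedom 7.83 and 7.67), and without it 3628 proteins were called higher and 3595 lower. Scaling by library totals moved the median log2 change of all R10 proteins from -0.01 to -0.16 and the share of calls that were higher from 49.5% to 31.6%.

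MW3 had the most changed proteins of the 4 strains. Protein 12179 had no read in any FLM library and 101 to 107 reads in each ECM library (12.7 ± 0.724 CPM, n = 3), at least 148-fold higher against a floor of 3 pooled reads. Protein 688067, also named in R10, rose from 4.83 ± 0.540 to 698 ± 96.4 CPM, 144-fold higher. Protein 23587 fell from 17.1 ± 1.87 CPM to no read in any ECM library, at least 140-fold lower, and protein 646616 fell from 75.3 ± 2.65 to 0.280 ± 0.127 CPM, a ratio of pooled reads of 263 (95% interval 127 to 655). Outside MW3, no library held over 2 reads of 23587 or over 3 reads of 646616, in either tissue. Their falls therefore cannot be compared with the other strains. With 1 library fewer the floor is higher, and the bound was 93.8 for 12179 without FLM replicate 3, and 90.8 and 91.8 for 23587 without ECM replicates 2 and 3. The 1158 proteins that rose at least 2-fold took 4.87% of the reads in FLM and 18.4% in ECM, and the 1152 that fell at least 2-fold took 27.4% and 7.71%. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment the 4 named proteins had adjusted p values of at most 1.84e-08, and 4491 proteins were higher and 4538 lower of 12440 tested (72.6%), 44.8% of them under 1.5-fold. Scaling by library totals moved the median log2 change of all MW3 proteins from 0.02 to 0.20 and the share of calls that were higher from 49.7% to 62.9%.

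**Figure D2:**
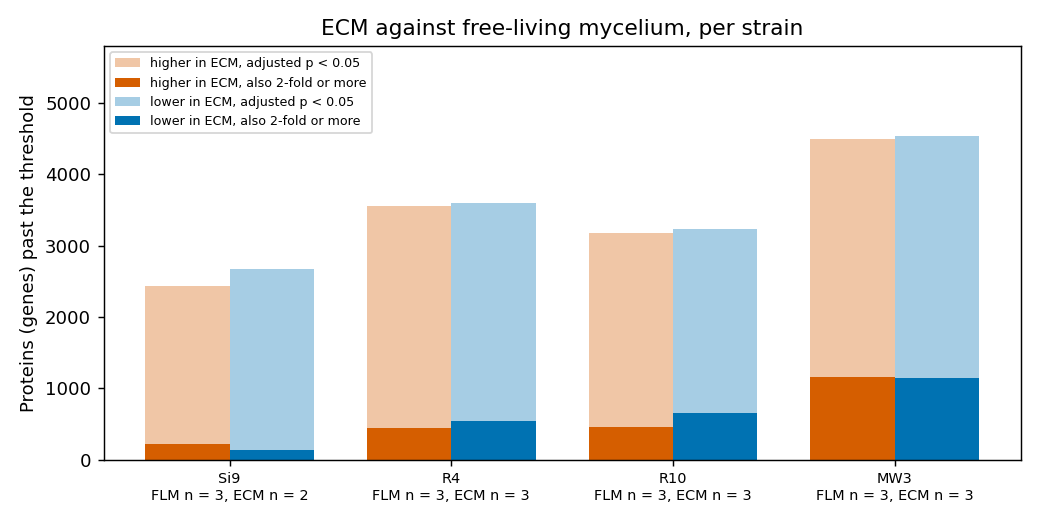
Number of proteins higher (orange) or lower (blue) in ECM than in FLM per strain, with pale bars for an adjusted p under 0.05 and dark bars for those also changed at least 2-fold. The 2-fold counts run from 228 higher and 140 lower in Si9 to 1158 higher and 1152 lower in MW3.

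A set of proteins moved in the same direction in every strain. Protein 466641 rose in ECM by 5.96-fold in Si9, 21.9-fold in R4, 19.8-fold in R10 and 6.50-fold in MW3. Protein 6861 rose by 12.3-fold, 31.5-fold, 18.2-fold and 5.11-fold in the same order. Protein 636179 was 5.29-fold lower in Si9, 11.01-fold in R4, 41.7-fold in R10 and 37.2-fold in MW3, and protein 675746 was 4.39-fold, 4.20-fold, 5.40-fold and 10.3-fold lower. Of 11287 proteins tested in all 4 strains, 340 were higher in every strain and 465 lower in every strain, against 69.5 and 80.3 for independent lists and 86.7 and 144 for lists independent within bins of the expression level. At least 2-fold in every strain, 28 rose and 18 fell, against 0.022 and 0.021. The edgeR quasi-likelihood test gave the 4 named proteins Benjamini-Hochberg adjusted p values of at most 2.81e-13 in each strain. The sizes of their changes differed between strains (edgeR quasi-likelihood test of equal change, Benjamini-Hochberg adjusted p of at most 1.10e-06).

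Most proteins past the threshold in every strain did not move one way. Of 2134 such proteins, 805 (37.7%) had 1 direction, where evenly split independent directions give 12.5%. Called in opposite directions in at least 1 pair of strains were 4446 proteins (39.4%), and 163 were at least 2-fold higher in 1 strain and at least 2-fold lower in another.

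**Figure D3:**
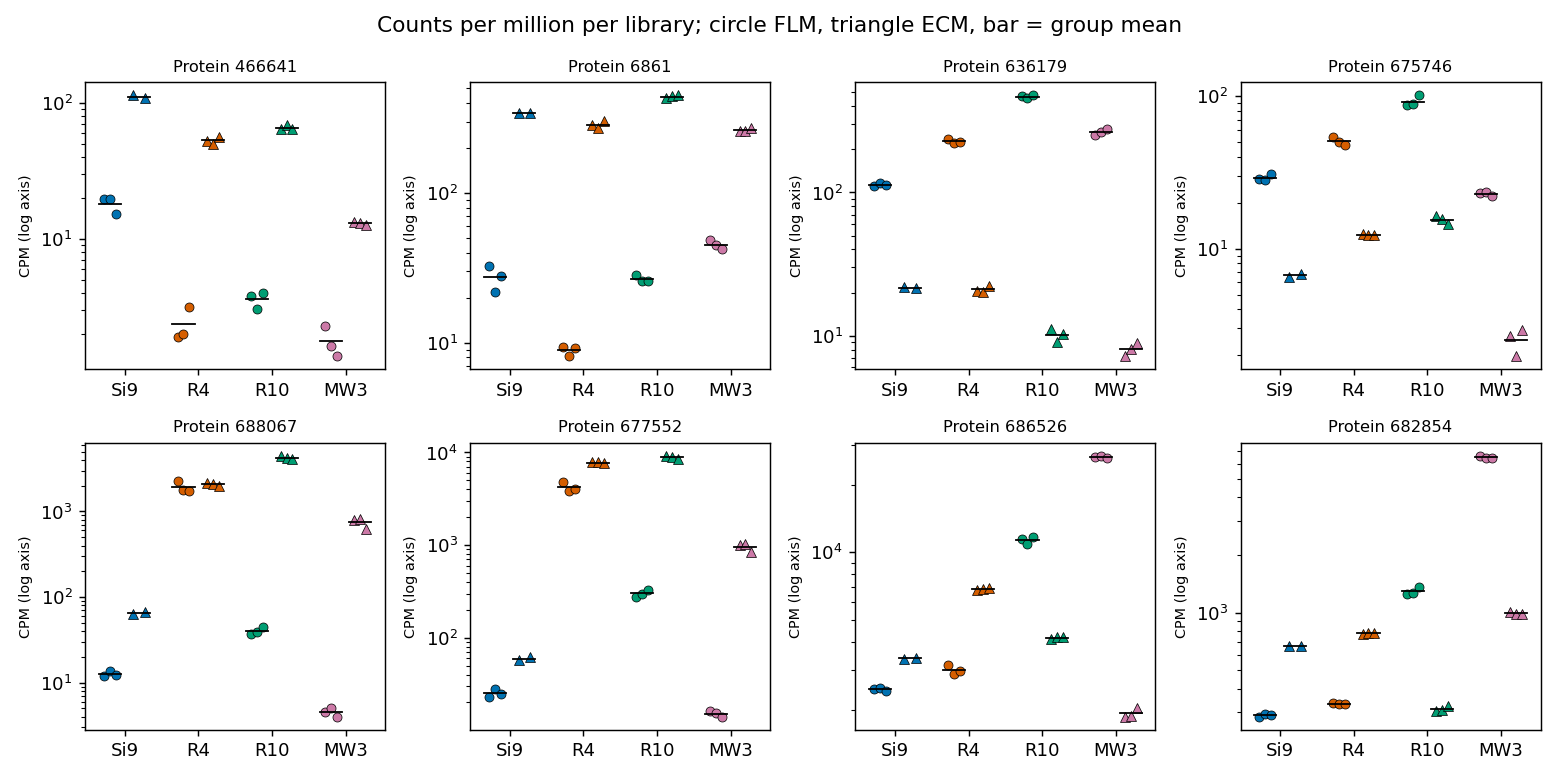
CPM per library (log axis, by library totals without TMM) of 8 named proteins in each strain, with circles for FLM, triangles for ECM and bars for group means. Proteins 466641 and 6861 were higher and 636179 and 675746 lower in ECM in every strain, while 686526 and 682854 were higher in ECM in Si9 and R4 and lower in R10 and MW3.

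The changes of R10 and MW3 had the highest correlation of the 6 pairs. Across proteins tested in both, their log2 changes correlated at Pearson r = 0.571 (Spearman rho 0.451), and 76.1% of the proteins called in both moved the same way. R4 and R10 came next (r = 0.427, rho 0.311, 70.5%), followed by Si9 and R4 (r = 0.242, rho 0.228, 67.0%). For Si9 and R10 (r = 0.190, rho 0.0991, 58.1%), R4 and MW3 (r = 0.189, rho 0.0884, 53.0%) and Si9 and MW3 (r = 0.168, rho 0.0540, 51.3%) the values were lower. These 6 correlations are across genes, which are not independent replicates. With no filter on low counts, r lay between 0.0922 (Si9 and R10) and 0.381 (R10 and MW3), so the order of the lower pairs depends on the filter.

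**Figure D4:**
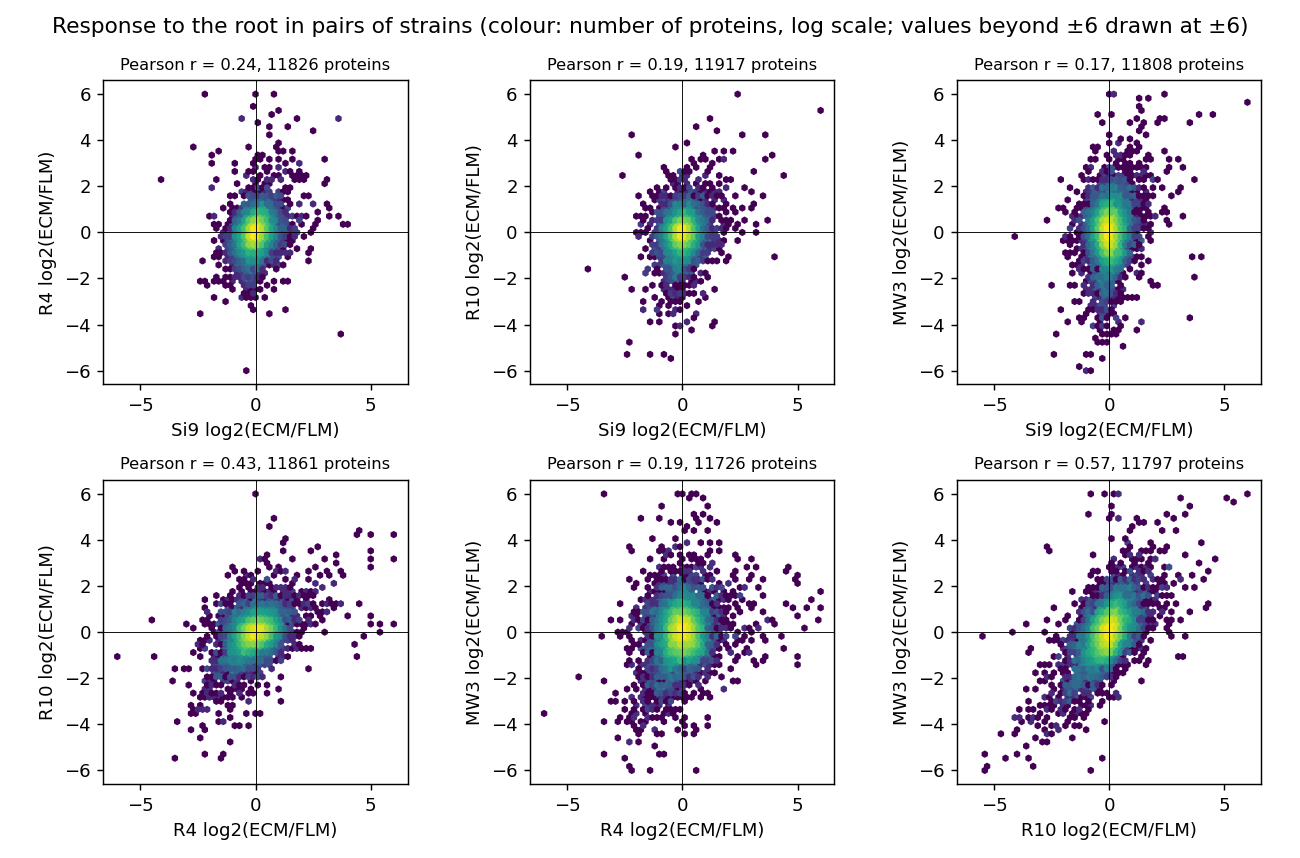
Log2 change from FLM to ECM in each pair of strains, coloured by the number of proteins on a log scale, with values beyond 6 in size drawn at 6. With low counts filtered, the cloud lies most along the diagonal for R10 and MW3 (r = 0.571) and least for Si9 and MW3 (r = 0.168).

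Testing the difference between strains directly gave proteins with opposite responses. Protein 686526 rose 1.37-fold in Si9 and 2.24-fold in R4, and was 2.46-fold lower in R10 and 15.8-fold lower in MW3, where it fell from 28407 ± 226 to 1802 ± 88.0 CPM (n = 3 each). Protein 682854 rose 2.29-fold in Si9 and 2.28-fold in R4, and was 3.74-fold lower in R10 and 7.46-fold lower in MW3. The edgeR quasi-likelihood test of equal change in all strains, with Benjamini-Hochberg adjustment, gave both an adjusted p of at most 8.78e-61. It called 10150 of 13830 proteins (73.4%), of which 5120 had changes at least 2-fold apart between some pair of strains. Taken in pairs, the changes differed at least 2-fold in 1156 proteins between Si9 and R4, the fewest, and in 3144 between R4 and MW3, the most.

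The strains also differed without a root. Levels compared between strains here are CPM by library totals, without TMM. In FLM, protein 56564 stood at 13430 ± 266 CPM in MW3, against 521 ± 14.9 in R10, 316 ± 9.37 in Si9 and 63.0 ± 1.79 in R4 (n = 3 each). Protein 682854 stood at 6497 ± 71.0 CPM in MW3 and 1293 ± 54.8 in R10, against 334 ± 2.25 in R4 and 290 ± 4.64 in Si9. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave both an adjusted p of at most 2.19e-40, and called 13181 of 13865 proteins (95.1%), 7831 of them with strains at least 2-fold apart. Pairs of strains differed at least 2-fold in 2789 proteins (R4 and R10) to 4457 (R4 and MW3). As all strains were counted on 1 gene set, sequence differences can shift these counts.

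In ECM, protein 677213 stood at 1976 ± 34.1 CPM in R10 (n = 3), against 139 ± 6.22 in MW3 (n = 3), 105 ± 3.08 in R4 (n = 3) and 88.6 ± 3.25 in Si9 (n = 2). Protein 684304 stood at 653 ± 18.6 CPM in R10 and 96.8 ± 4.30 in R4, while libraries of Si9 held 0 to 3 reads and those of MW3 held 1 to 4. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment both had an adjusted p of at most 3.29e-142, and 12656 of 13518 proteins (93.6%) differed between strains, 6920 of them at least 2-fold. Pairs of strains differed at least 2-fold in 2898 proteins (R4 and R10) to 3925 (Si9 and R10). The same limit of a shared gene set holds here, and these levels are also CPM by library totals.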

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

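Tests chosen only after the data or results were seen were those at equal depth, with length trends removed, of the falling proteins, of the spread between replicates and all 3 on R10 FLM replicate 3. The response to the root differed between strains in 10150 proteins by a test of the difference itself. The gap between the largest and the smallest log2 change among strains was 10.6 for protein 17110, 8.61 for 685512 and 8.15 for 25241, each with a group at under 10 reads per library. Leaving out R4 FLM replicate 2 gave 11.4 for 17110, and leaving out R4 FLM replicate 3 gave 9.73 for 685512. The gap was 7.09 for 688067, 6.48 for 686019 (an uncertain value, as its reads may be shared with similar genes), 6.41 for 572741, 5.31 for 11043, 5.14 for 686526 and 4.95 for 677552. Gaps of 4.55 for 56564, 4.09 for 682854, 3.89 for 677213 and 2.98 for 636179 were also past the threshold. Proteins 6861 (2.62), 466641 (1.88) and 675746 (1.30) moved the same way in every strain with sizes that differed. In the TPM values, which no comparison used, 285 proteins with no unique read in any library had a TPM above 0.

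The proteins that moved the same way in all 4 strains were tested against technical sources. With every library thinned to the same depth, 39.9% of proteins called in all strains moved one way, and with length trends removed 35.2% did, both far above 12.5%. The log2 change fell weakly with gene length in every strain (Spearman rho -0.168 in Si9, -0.136 in R4, -0.0377 in R10 and -0.0889 in MW3). With length trends removed, 304 of the 340 proteins higher in every strain stayed so, and 366 of the 465 lower. A length trend may therefore account for part of the set. Plant reads counted on fungal genes lower other genes only by diluting all of them alike. Scaled by library totals, 18 proteins fell at least 2-fold in every strain (0.0189 for independent lists). The median log2 change of all proteins was -0.16 to 0.20, which argues against plant reads for these 18 proteins. Of the 465 proteins lower in every strain, 377 stayed so with that scaling. For the smaller falls plant reads stay open. For the proteins that rose, plant reads also stay open. The smallest interquartile range of the log2 ratio of added CPM between strains was 1.58. Setting it against a narrow range assumed the same plant profile under all strains, which was not measured. A response to the root common to the strains also stays open, as a hypothesis.

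MW3 changed most and Si9 least. At the same depth and with ECM replicates 1 and 3 only, MW3 had 6.12 times as many proteins called and changed at least 2-fold as Si9. The ratio was 7.44 for group means 2-fold apart with no test, and 6.13 with length trends removed. Depth, the number of libraries, replicate spread and gene length therefore do not account for the gap in 2-fold changes. Without the 2-fold minimum the gap was smaller, with 7605 calls in MW3 and 4194 in Si9 at the same depth and with the same ECM replicates. The conclusion covers 2-fold changes only. A strain difference is a hypothesis, and sequence differences from the shared gene set were not tested as a source.

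R10 FLM replicate 3 differed from replicates 1 and 2 along gene length, with a Spearman rho across proteins of -0.439, where libraries outside that group reached at most 0.243 in size. A first test of R10 ECM RNA mixed into it did not decide, as the implied share was -0.857% from proteins at least 4-fold lower in ECM and 0.624% from those at least 4-fold higher, with 95% intervals of -4.63 to 1.08 and 0.0505 to 1.08. A further test, chosen because that first test did not decide, found that the largest share allowed (1.08%) would give 7.58% of the observed SD of the deviations, which argues against mixing as the whole source. A small admixture stays open, as only the interval from the proteins higher in ECM excludes 0. A length trend from library preparation or RNA quality may be part of the difference, and no biological explanation was tested.

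Splitting the 6 libraries of a strain in other ways gave 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 7158 proteins in R4, 6417 in R10 and 9029 in MW3, and the highest other split called 0 in each. Those other splits put ECM and FLM libraries in the same group, which widens the spread, so few calls were likely from the start. For the FLM strain differences the real split was the only 1 of 100 with as many calls (13181), the highest other calling 2235. The other splits mixed strains within groups, which widens the spread and lowers the calls. The result argues only against a random assignment of these libraries to strains, and does not address batches or whether the libraries were separate samples.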

How the results depend on the processing

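Length correction, equal depth and total-count scaling were chosen after seeing the data. Across settings 276 of the main values stayed within their limits and 26 did not, and all 488 values of named proteins kept direction and threshold side. With a 2-fold minimum, counts higher and lower were 228 and 140 (Si9), 452 and 542 (R4), 461 and 661 (R10), 1158 and 1152 (MW3) and 28 and 18 (every strain), and the joint tests gave 5120 (response), 7831 (FLM) and 6920 (ECM), since small changes no longer count. Leaving out 1 library at a time, Si9 proteins lower in ECM numbered 1717 to 2512, the lowest without ECM replicate 3, which leaves 1 ECM library. Correlations between strains became, by Spearman, 0.228 (Si9 and R4), 0.0991 (Si9 and R10), 0.0540 (Si9 and MW3), 0.311 (R4 and R10), 0.0884 (R4 and MW3) and 0.451 (R10 and MW3), and with no low filter 0.128, 0.0922, 0.124, 0.289, 0.0989 and 0.381, and the cause was not tested. The replicate number as a block gave 2300 higher and 2470 lower (Si9), 3632 and 3660 (R4), 3226 and 3278 (R10) and 4483 and 4528 (MW3), and moved no count over 1.5 times. Deviations of the 11 same-numbered pairs correlated at -0.0206 to 0.0949, under the limit of 0.1. Counting noise lowers such correlations, so they do not decide whether the numbers pair the samples. Gene list alternatives were not run, as no list had members. At equal depth (5046321 reads per library) the calls in Si9 numbered 2104 higher and 2120 lower.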

Other observations

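Both tests below were chosen after the results were seen. In both R10 and MW3, 35 proteins rose at least 4-fold in ECM. Of these, 15 also rose at least 2-fold in R4 and 19 in Si9, and 17 were among the proteins higher in every strain, 10 of them at least 2-fold. A hypothesis is that some of them may already be expressed in R4 mycelium without a root. The idea came from the R4 levels of proteins 688067 (1925 ± 284 CPM in R4 FLM against 12.7 ± 0.851 in Si9 FLM, n = 3 each) and 677552 (4218 ± 545 against 25.4 ± 2.61). These levels are CPM by library totals, without TMM. The median log2 ratio of R4 FLM to Si9 FLM was 2.02 over the 35 proteins, 24 of them higher in R4, where the central 95% of 10000 random lists matched on expression level lay between -0.20 and 0.33. Without the 2 proteins that prompted the idea, the median over 33 proteins was 1.77 (22 higher in R4, random lists -0.22 to 0.33). The random lists were not matched on how strongly proteins changed, and proteins that change strongly may also differ more between strains. Sequence differences between strains and the shared gene set were not tested here.

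MW3 stood closer to the other strains in root tips than in free-living mycelium. At equal depth, the SD across proteins of its log2 difference from each other strain was smaller in ECM, with ratios of ECM to FLM of 0.936 (Si9), 0.864 (R4) and 0.938 (R10). The same ratio was 1.10 for Si9 and R10, 1.03 for R4 and R10 and 0.963 for Si9 and R4. The 10 most abundant proteins of MW3 took 9.52% ± 0.100 of the reads in FLM and 5.82% ± 0.066 in ECM (SD, n = 3 each).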
